A study of Mus musculus with 3 samples.

How the data were processed

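TCF21 occupancy was measured by ChIP-seq in 3 samples of cardiac fibroblasts from male and female Col1a1-TCF21 mice, labelled as replicates 1, 3 and 4 of 1 group. Per the labels' protocols, each sample held the fibroblasts of 3 mice, infected with an adenovirus for Cre to switch on TCF21, grown for 5 days to fill 4 dishes of 10 cm, and given 10 ng/mL TGF-β1 for the last 24 hours. Chromatin was cut to fragments of 400 to 800 bp. The antibody is not given in the sources used here, and libraries of control chromatin or of cells without induction were not analysed here.

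Per the series' design text, the authors trimmed adapters with Trim Galore, aligned paired reads to mm10 (GRCm38) with Bowtie and called peaks with MACS2 in a SciDAP workflow; the versions are not given in the sources used here. The deposited peak lists give, for every summit, a score that equals 10 times the −log10 q cut to a whole number. The fold enrichment is a ratio computed by the authors of the signal at the summit over background. The −log10 p and −log10 q values are those deposited by the authors, and a last column, deposited as an offset in bp, places the summit within the peak. In every list each fold had a single p (0 folds had several), and folds were whole multiples of 1 step (0.495, 0.325 and 0.471 in replicates 1, 3 and 4), which fits scoring against 1 background value per library. Whether peaks were called against control chromatin is not given in the sources used here, and they may have been called without it. The lowest −log10 q was 3.41, 3.26 and 3.42. The peak lists hold no read counts, so depth and the precision it gives are unknown.

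Peaks on chromosomes 1 to 19, X and Y were used for everything after the counts, with the GRCm38.p6 chromosomes and the GENCODE vM21 annotation, the build the authors used. Summits of the same interval formed 1 peak region. Overlapping regions of the 3 lists (at least 1 bp) were merged, and a merged region with a peak of every library was a consensus region. Overlap between libraries was compared with 1000 random placements of each list on its own chromosomes (one-sided permutation test). Summits were assigned to promoters (1000 bp either side of the start of a protein-coding transcript), exons, introns or intergenic sequence and compared with 1000 random placements (two-sided permutation test).

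Motif content was the share of windows of 100 bp either side of a summit with a match on either strand, divided by the share in windows centred 1000 bp away on both sides. The motifs were the 10 E-box types and 17 other fixed motifs, tested in each library by the two-sided Fisher's exact test over windows, and all 2080 6-base words were ranked in the same way. Windows of a library are not independent samples, so a motif was called only where all 3 libraries passed an adjusted p of 0.05 in the same direction. The same test compared promoter with distal summits, and summits in regions of 3 libraries with those of 1. All p-values were adjusted by Benjamini-Hochberg.

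Gene lists were compared with 10000 random lists of protein-coding genes of the same size, matched on gene length in 20 bins (two-sided permutation test). The measures were the share of genes with a consensus region within 1000 bp of a transcript start, and the mean log2 of 1 plus the number of consensus regions in the gene body extended by 10000 bp. The 22 lists were matrix, matrix remodelling, TGF-β signalling, contractile and myofibroblast, fibroblast identity, bHLH and Id factors, AP-1 and related bZIP factors, Hippo pathway and YAP targets, integrins and adhesion, Wnt signalling, cell cycle, inflammatory, osteochondrogenic, adipogenic, cardiomyocyte, endothelial, macrophage and lymphocyte, smooth muscle and pericyte, epicardial and mesothelial, neuronal, olfactory receptors and ribosomal proteins. Of 538 listed genes 537 were found in the annotation.

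The groups, tests, lists, motifs, main settings and most alternatives were fixed before the data were examined. So was the rule for named genes: the gene nearest to each of the 10 highest consensus regions by mean rank of fold, the 3 genes of each list (leaving out olfactory receptors and ribosomal proteins) with the highest region at the promoter or else in the locus, and 12 genes named whatever their values. Some genes that the rule names are not reported here. The alternatives were peaks of −log10 q of at least 10, equal list lengths, leaving out each library, overlap of 50% of both peaks, summits within 200 bp, peaks shifted by 10000 to 50000 bp, promoters of 2500 bp, transcripts of all genes, windows of 50 bp, shuffled summit sequence with dinucleotides kept, loci of 50000 bp and a background of genes with a peak. Further settings were chosen after seeing the data: only the best summit of each region, multi-copy consensus regions left out, and random lists matched on promoter GC too. A region was multi-copy where more than 10% of its 32-base words occurred elsewhere in the chromosomes. The highest single-copy regions also had less than 50% of bases masked as repeats and lay at least 100000 bp from any multi-copy region among the highest.

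The methods were tested on simulated data. For the overlap of replicate 1 with replicate 4, planted shares of 0, 20 and 60% gave −0.108, 19.9 and 59.6% above chance. For CAGCTG, 30.1% planted gave 30.2% recovered in 20000 windows. For the gene list comparison, 1.5% of random lists of 28 genes passed p 0.05 by promoter and 5.5% by locus, and 90% passed when promoter occupancy was raised by 20 points and 100% at 40 points. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.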

Results

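TCF21 is a basic helix-loop-helix transcription factor of the epicardium and of the fibroblasts that descend from it. Its genomic sites were mapped in 3 ChIP-seq libraries (replicates 1, 3 and 4) of mouse cardiac fibroblasts with induced TCF21, treated with TGF-β1 for the last 24 hours. Fibroblasts without induction, cells without TGF-β1 and control chromatin were not analysed here, so each result compares replicates with each other, summits with nearby or random sequence, or gene lists with matched genes. The lists held 48669, 71556 and 115174 summits in replicates 1, 3 and 4, in 41951, 58983 and 85877 peak regions covering 12.8, 12.3 and 26.04 Mb. Median fold enrichment was 6.44, 5.19 and 6.59; these fold values are the authors', given per peak, and are used only to rank and describe peaks within their own list.

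TCF21 occupied a shared set of sites in the fibroblasts of all 3 preparations, and these sites were stronger than the rest of each list. Merging the lists gave 129575 regions, of which 18714 (14.4%) held a peak of every library, 15194 of 2 libraries and 95667 (73.8%) of a single library. The 18714 shared regions, called consensus regions here, made up 47.4, 35.3 and 22.7% of the regions of replicates 1, 3 and 4. Their median fold was 7.92, 6.49 and 12.7, against 5.45, 4.54 and 5.65 in the other regions of the same lists. Their median width was 647 bp (quartiles 490 and 832 bp), and the 3 summits lay a median of 133 bp apart. Of the regions of replicate 1, 46.2% overlapped a region of replicate 3 (1.26% after random placement, 36.5-fold) and 64.7% a region of replicate 4 (2.14%, 30.2-fold). Of those of replicate 3, 34.2% overlapped replicate 1 (37.5-fold) and 47.7% replicate 4 (25.997-fold). Of those of replicate 4, 31.1% overlapped replicate 1 (29.2-fold) and 30.7% replicate 3 (24.4-fold). Every overlap had an adjusted p of 0.001 (one-sided permutation test), the smallest possible with 1000 placements. Across consensus regions the ranks of fold correlated between libraries (Spearman 0.64 for replicates 1 and 3, 0.69 for 1 and 4, 0.71 for 3 and 4). The number of consensus regions fell to 7353 with peaks of −log10 q of at least 10 and to 7525 when peaks had to overlap by 50% of both.

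TCF21 summits gathered at the promoters of protein-coding genes, while most of them lay in introns and between genes, where enhancers are found. Promoters, taken as 1000 bp either side of a transcript start, held 12.7 ± 3.33% of summits (n = 3; 12.3, 9.50 and 16.1% in replicates 1, 3 and 4) against 2.66% of random positions, a ratio of 4.76 ± 1.26. Exons held 4.41 ± 0.70% (1.73 times random, n = 3) and introns 42.2 ± 0.62% (1.13 times, n = 3), and intergenic sequence held less than random, 40.7 ± 2.37% against 57.5% (0.71 times, n = 3). The adjusted p was 0.002 for each class in each library, the smallest possible (two-sided permutation test). Random positions do not account for open chromatin, and without control chromatin its part in the promoter share was not separated from TCF21 binding. Among consensus regions 2669 (14.3%) lay in promoters, 728 (3.89%) in exons, 7920 (42.3%) in introns and 7397 (39.5%) between genes.

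The 6-base word most enriched at TCF21 summits was the palindromic E-box CAGCTG, although most summits did not have it. Basic helix-loop-helix dimers bind CANNTG, and the 2 central bases separate the members of the family. CAGCTG was present within 100 bp of 38.1 ± 2.39% of summits (n = 3) and in 10.4% of flanking windows, a ratio of 3.65 ± 0.28. It ranked first of all 2080 possible 6-base words. The words next in rank held CG pairs, led by CGCGGC (2.86 ± 0.31, n = 3). Summit windows were richer in GC than flanks (52.3 ± 0.60 against 46.5 ± 0.24%, n = 3), and flanks were not matched on GC. CATCTG followed among the E-boxes with 22.5 ± 0.43% against 15.8% (1.43 ± 0.02, n = 3). Ratios were smaller for CACGTG (1.27 ± 0.08, n = 3), CACCTG (1.13 ± 0.06, n = 3) and CAACTG (1.09 ± 0.02, n = 3). CATATG (0.88), CAAATG (0.81) and CAATTG (0.74) were rarer at summits than in flanks, and CAAGTG (0.98) and CACATG (1.01) were not called. A motif was called where every library passed an adjusted p of 0.05 in the same direction (two-sided Fisher's exact test). Shuffled summit sequence keeps the GC of the summits. With it in place of flanks, CAGCTG and CATCTG kept their direction. CAACTG over control (0.650) and CACCTG over control (0.808) turned lower, and CATATG over control (1.28) and CAAATG over control (1.03, not called) turned higher. CACCTG over control also fell below 1 with peaks of −log10 q of at least 10 (0.955, not called) and was not called at equal list lengths (1.07). CAGCTG and CATCTG together were densest within 20 bp of the summit, at up to 4.55, 4.36 and 4.12 sites per kb in replicates 1, 3 and 4.

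**Figure D1:**
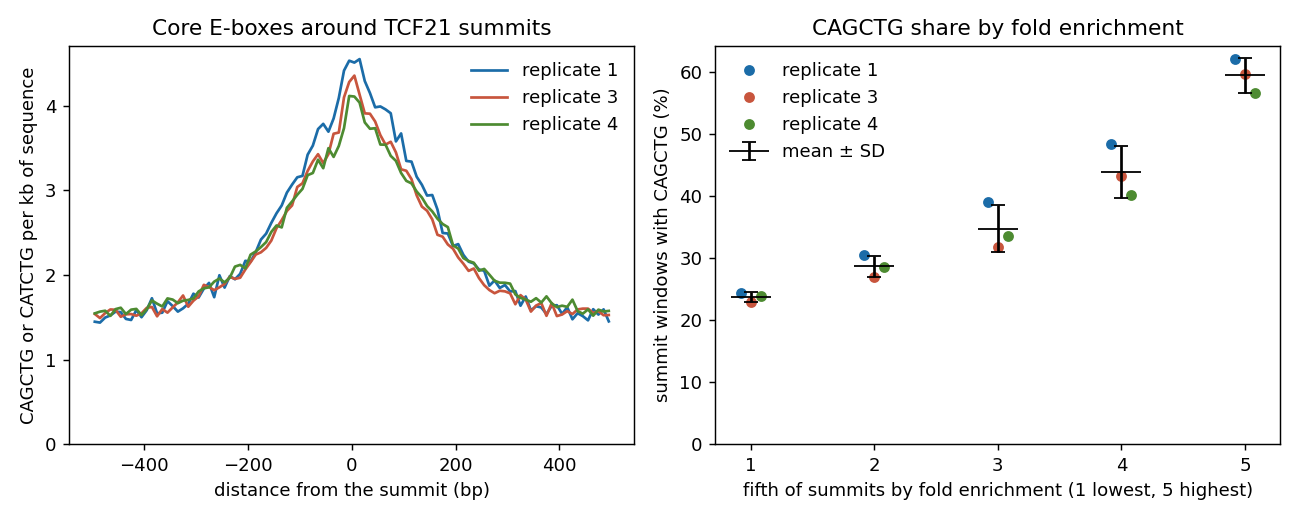
Sites of CAGCTG or CATCTG per kb (vertical axis) by distance from the TCF21 summit (horizontal axis, bp), 1 line per replicate. The density is highest close to the summit in all 3 libraries and declines on both sides.

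CAGCTG content rose with the strength of TCF21 sites, and sites shared by all 3 preparations held CAGCTG or CATCTG more often than those of 1. With summits ranked by fold and cut into 5 equal parts, CAGCTG was present at 23.7 ± 0.74, 28.6 ± 1.74, 34.7 ± 3.78, 43.8 ± 4.18 and 59.4 ± 2.77% of summits from the weakest to the strongest part (n = 3 each). Its ratio over flanks went from 2.39 to 5.44. CAGCTG or CATCTG was present at 37.8 ± 4.42% of summits in regions called in 1 library, 56.8 ± 2.07% in 2 and 62.7 ± 3.50% in all 3 (n = 3 each). The ratio of shared to single-library summits was 1.80, 1.86 and 1.37 in replicates 1, 3 and 4, each past an adjusted p of 0.05 (two-sided Fisher's exact test). Summits shared by 3 libraries were also compared with single-library summits within the same part of the fold range. The CAGCTG share of shared summits was higher by 18.9 ± 5.05 points in replicate 1, 29.0 ± 8.19 in replicate 3 and 2.08 ± 4.37 in replicate 4. This comparison by replicate was chosen after the values were seen. Its SDs are over the 5 parts, weighted equally, and not over samples. The strongest part of replicate 1 held 16 single-library and 9482 shared summits. Over the libraries the difference was 16.7 ± 13.6 points (n = 3).

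Motifs of other fibroblast regulators were also more frequent at TCF21 summits as a whole than in flanks. AP-1 factors and TEAD factors, the DNA-binding partners of YAP and TAZ, drive enhancers in activated fibroblasts, and SMAD proteins carry the TGF-β signal to DNA. The AP-1 site was present at 8.96 ± 0.93% of summits against 3.68% of flanks (2.43 ± 0.22, n = 3) and the TEAD site at 14.3 ± 0.30% against 10.8% (1.32 ± 0.03, n = 3). The CAGA element of SMAD proteins reached 23.0 ± 0.71% against 19.4% (1.19 ± 0.04, n = 3) and the palindromic SMAD element 0.297 ± 0.020% against 0.190% (1.56 ± 0.10, n = 3). NRF1 (3.54 ± 0.53), CTCF (3.28 ± 0.56), SP and KLF (2.07 ± 0.21), ETS (1.43 ± 0.07), NFI (1.26 ± 0.02) and RUNX (1.1 ± 0.04) sites were also more frequent at summits (n = 3 each). Forkhead (0.66 ± 0.05), CCAAT (0.87 ± 0.02) and STAT (0.89 ± 0.04) sites were rarer (n = 3 each), and the CArG box of SRF (0.91), C/EBP (1.02), GATA (1.00) and MEF2 (0.82) sites were not called. With shuffled summit sequence as control, the palindromic SMAD element over control was no longer called (1.07). NFI site over control turned lower (0.867), C/EBP over control was called lower (0.724), and forkhead over control (1.77), STAT over control (1.36) and MEF2 over control (2.78) turned higher. With peaks of −log10 q of at least 10, the palindromic SMAD element over control (1.58) and STAT over control (0.906) were no longer called.

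**Figure D2:**
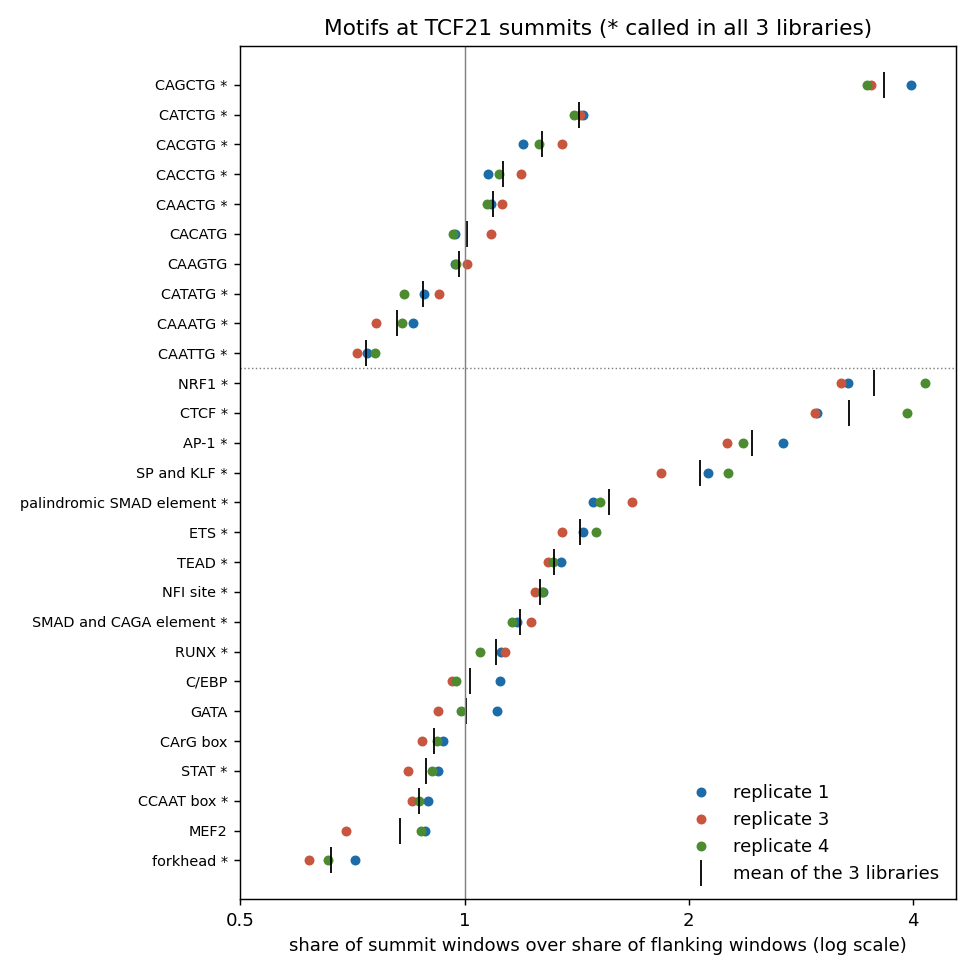
Share of summit windows with each motif divided by the share in flanking windows, with 1 point per replicate. CAGCTG lies highest of the E-boxes, and NRF1, CTCF and AP-1 sites highest of the other motifs.

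Promoter and distal TCF21 sites differed in the motifs around them, whereas CAGCTG went in opposite directions in the libraries. SP and KLF sites, typical of CpG-rich promoters, were present at 20.8 ± 2.27% of promoter summits and 2.42 ± 0.31% of distal ones (8.63 ± 0.24, n = 3), and NRF1 sites at 2.43 ± 0.33 and 0.126 ± 0.015% (19.3 ± 1.43, n = 3). Distal summits had more AP-1 sites (9.65 ± 1.1 against 4.36 ± 0.67%, ratio of promoter to distal 0.45 ± 0.08, n = 3), TEAD sites (14.97 ± 0.50 against 9.53 ± 0.62%, 0.64 ± 0.06, n = 3), RUNX sites (17.9 ± 0.49 against 10.6 ± 0.91%, 0.59 ± 0.03, n = 3) and CAGA elements (0.62 ± 0.05, n = 3). Against their own flanks, promoter summits had fewer TEAD sites (0.93 ± 0.05), CAGA elements (0.89 ± 0.07), RUNX sites (0.78 ± 0.04) and NFI sites (0.92 ± 0.04; n = 3 each). They still had more AP-1 sites (1.36 ± 0.19), SP and KLF sites (3.41 ± 0.16) and NRF1 sites (6.93 ± 0.69; n = 3 each). Flanks of promoter summits also held more SP and KLF sites than flanks of distal ones (6.09 against 1.73%), and more NRF1 sites (0.353 against 0.083%). These comparisons with flanks are given without a test. CATCTG was also a distal E-box, at 23.8 ± 0.26% of distal and 13.99 ± 1.26% of promoter summits (0.59 ± 0.06, n = 3), and CACGTG was more frequent at promoters (1.49 ± 0.08, n = 3). CAGCTG was present at 37.6 ± 7.14% of promoter and 38.3 ± 2.39% of distal summits (n = 3) and was not called. Its promoter to distal ratio was 0.983 in replicate 1 (adjusted p 0.328), 1.19 in replicate 3 (adjusted p 9.9e-28) and 0.779 in replicate 4 (adjusted p 8.4e-107; two-sided Fisher's exact test for all). CAGCTG or CATCTG together, at 46.8 ± 7.46 and 53.4 ± 2.07% (0.88 ± 0.15, n = 3), was not called either. For promoter against distal summits it was called lower at promoters with peaks of −log10 q of at least 10 (0.857) and without replicate 3 (0.805).

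Matrix genes had TCF21 at their promoters more often than genes of the same length under every setting tried, and 4 further lists did so under the main setting. Of 21826 protein-coding genes, 2863 (13.1%) had a consensus region within 1000 bp of a transcript start and 8321 (38.1%) had at least 1 in the gene body or within 10000 bp of it. Random lists were drawn from all of these genes, and genes silent in fibroblasts were not left out. Open chromatin and gene activity were not matched, so their part in either list measure was not separated from TCF21 binding. The number of transcript starts per gene was not matched either, and genes with more starts have more chances of an occupied promoter. Promoters were occupied in 11 of 28 matrix genes (39.3 against 15.7% in length-matched lists, adjusted p 0.00983) and 13 of 29 contractile and myofibroblast genes (44.8 against 14.8%, adjusted p 0.0022; two-sided permutation test for all lists). They were occupied in 11 of 28 TGF-β signalling genes (39.3 against 15.5%, adjusted p 0.00821; permutation test), 9 of 27 matrix remodelling genes (33.3 against 13.7%, adjusted p 0.0401) and 8 of 18 genes of AP-1 and related factors (44.4 against 12.4%, adjusted p 0.0044; permutation test). With peaks of −log10 q of at least 10, the calls of contractile and myofibroblast promoter (adjusted p 0.0786), TGF-beta signalling promoter (adjusted p 0.926), matrix remodelling promoter (adjusted p 0.474) and AP-1 and related bZIP promoter (adjusted p 0.56) occupancy were lost in the same permutation test. The matrix list kept its call. With random lists matched on promoter GC as well as length, an alternative chosen after seeing the data, the matrix remodelling (adjusted p 0.154), TGF-β (adjusted p 0.0996) and AP-1 (adjusted p 0.0863) lists were not called by the permutation test. The same lists were lost against genes with a peak, with adjusted p of 0.0807 for matrix remodelling promoter, 0.0539 for TGF-beta signalling promoter and 0.0802 for AP-1 and related bZIP promoter occupancy (permutation test). The TGF-β list was also lost at equal list lengths (adjusted p 0.084, permutation test) and the remodelling list without replicate 1 (adjusted p 0.163, permutation test).

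The genes named for each list are the 3 with the highest mean rank of fold over the libraries, taken from occupied promoters first. The values given for them are the mean ± SD of the percentile rank of the region within each list, where 100 is the highest. A promoter counted as occupied when a consensus region reached within 1000 bp of a transcript start, so the summit itself could lie further away, as at Thbs1 (1213 bp) and Tagln2 (1540 bp). Any protein-coding transcript start of a gene counted, including starts inside it. The regions at Palld, Cnn3, Smad3, Ltbp1 and Mafk lay near such internal starts, away from the start of the gene itself. Among matrix genes the highest-ranked promoters were those of Emilin1 (mean percentile rank 98.7 ± 0.129), Vcan (97.9 ± 0.833) and Thbs1 (97.3 ± 1.37; n = 3 for each gene). Among remodelling genes they were those of Mmp2 (96.2 ± 2.71), Pcolce, which encodes an enhancer of procollagen cleavage (94.4 ± 5.04), and the crosslinking enzyme gene Loxl1 (86.8 ± 5.09; n = 3 for each gene). The highest-ranked contractile promoters were those of Tagln2 (96.5 ± 3.16), Palld (95.1 ± 1.06) and Cnn3 (95.03 ± 0.158; n = 3 for each gene). TGF-β promoters ranked highest at Smad3 (98.0 ± 0.835), Skil (86.5 ± 4.27) and Ltbp1 (85.2 ± 7.32), and AP-1 promoters at Jund (96.9 ± 2.07), Fosl2 (96.7 ± 3.06) and Mafk (77.2 ± 18.2; n = 3 for each gene).

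Counting every consensus region in a gene and its surroundings widened this set to adhesion, Hippo and fibroblast identity genes. The mean log2 of 1 plus the number of regions was 1.82 for integrins and adhesion genes against 0.86 in length-matched lists. It was 1.68 against 0.76 for matrix, 1.53 against 0.74 for the Hippo pathway and YAP targets, 1.53 against 0.75 for contractile genes and 1.5 against 0.74 for TGF-β signalling. Fibroblast identity (1.27 against 0.51), matrix remodelling (1.25 against 0.56), AP-1 (1.15 against 0.44) and bHLH and Id genes (1.07 against 0.46) were higher as well. These 9 lists had an adjusted p of 0.0008 (two-sided permutation test), the smallest adjusted value. Inflammatory genes (0.98 against 0.49, adjusted p 0.0044) and smooth muscle and pericyte genes (1.08 against 0.56, adjusted p 0.00983) were also called by the permutation test. With peaks of −log10 q of at least 10, the smooth muscle and pericyte locus (adjusted p 0.236) and AP-1 and related bZIP locus (adjusted p 0.546) calls were lost in the permutation test.

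Promoters of these lists were ranked in the same way. The highest-ranked Hippo promoters were those of the kinase gene Lats2 (99.4 ± 0.652), Tead1 (99.4 ± 0.217) and the TEAD cofactor gene Vgll3 (95.5 ± 2.35; n = 3 for each gene). Adhesion promoters ranked highest at the focal adhesion kinase gene Ptk2 (95.6 ± 0.725), Itgb5 (86.2 ± 6.71) and Bcar1 (84.9 ± 5.37; n = 3 for each gene). Fibroblast identity promoters ranked highest at S100a4 (98.2 ± 0.464), Dpt (96.9 ± 1.40) and Mfap4 (96.0 ± 0.717; n = 3 for each gene). Among the bHLH family and its Id inhibitors, the highest-ranked promoters were those of Id2 (96.4 ± 1.45), Hes1 (94.2 ± 3.93) and Id1 (90.4 ± 5.62; n = 3 for each gene). Stat3 (86.4 ± 3.91) and Csf1 (80.2 ± 12.05) were among the 3 highest-ranked inflammatory promoters (n = 3 for each gene). Smooth muscle promoters ranked highest at Map3k7cl (89.8 ± 7.74), Ndufa4l2 (84.2 ± 9.81) and Foxs1 (81.6 ± 12.3; n = 3 for each gene). The summits lay 1393 bp from the transcript start at Tead1, 1680 bp at Id2 and 1359 bp at Ndufa4l2. The promoter held a peak of its own in 2 libraries at Tead1 and in only 1 at Ndufa4l2. The regions at Tead1, Itgb5, Bcar1 and Csf1 lay near transcript starts inside the gene. By promoter occupancy, fibroblast identity (7 of 28 genes, adjusted p 0.221), bHLH and Id (7 of 24, adjusted p 0.0594), Hippo (7 of 25, adjusted p 0.246), integrin (7 of 25, adjusted p 0.342), inflammatory (8 of 27, adjusted p 0.0754) and smooth muscle lists (6 of 21, adjusted p 0.176) were not called (two-sided permutation test).

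**Figure D3:**
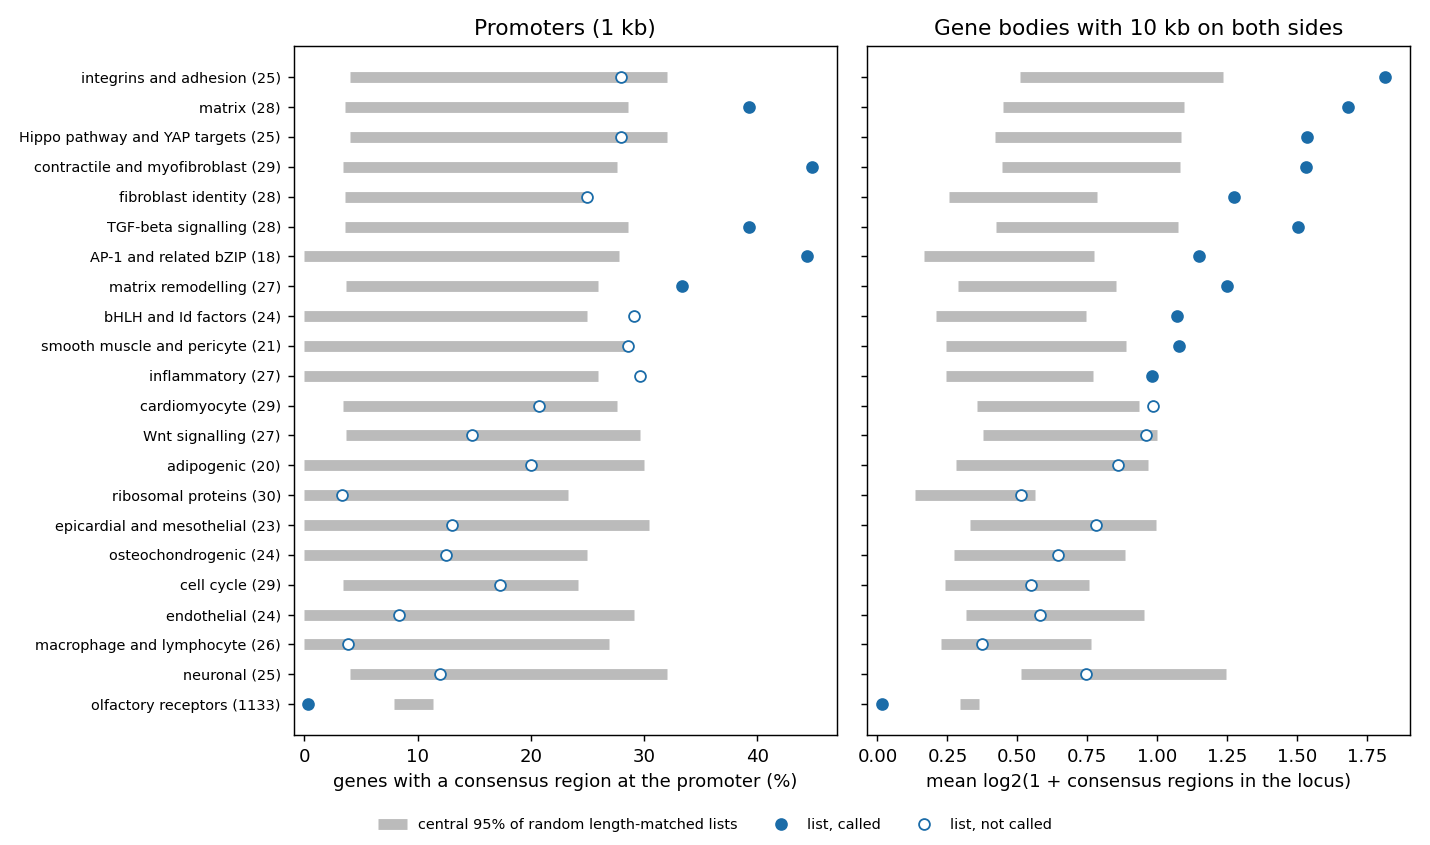
Promoter occupancy and the locus measure of each fixed gene list (points) beside the range of length-matched random lists (bars). Matrix, matrix remodelling, contractile, TGF-β signalling, AP-1, bHLH and Id, and inflammatory genes lie above that range on both measures, and olfactory receptors lie below it. The bHLH and Id list and the inflammatory list were not called by promoter occupancy.

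Genes of most other lineages and of general cell functions were not called on either measure. Endothelial genes had 2 of 24 promoters occupied and a locus measure of 0.58 against 0.62, macrophage and lymphocyte genes 1 of 26 and 0.38 against 0.48, and neuronal genes 3 of 25 and 0.75 against 0.87. Cardiomyocyte genes had 6 of 29 promoters occupied. The cardiomyocyte locus measure of 0.99 against 0.64 (adjusted p 0.057, two-sided permutation test) was called at equal list lengths (adjusted p 0.0361). Wnt signalling (4 of 27 promoters), cell cycle (5 of 29), osteochondrogenic (3 of 24), adipogenic (4 of 20), epicardial and mesothelial (3 of 23) and ribosomal protein genes (1 of 30) were not called. Olfactory receptors, silent in most tissues, had 4 of 1133 promoters occupied (0.353 against 9.60%, adjusted p 0.0008, two-sided permutation test) and a locus measure of 0.01 against 0.33.

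Single promoters of these lists still had TCF21 sites. The highest-ranked promoters were Tubb3 (99.7 ± 0.146), Camk2a (96.7 ± 3.34) and Rbfox3 (66.9 ± 10.5) of the neuronal list (n = 3 for each gene). Others were Cacna1c (95.3 ± 4.07) and Myl4 (95.1 ± 1.46) of the cardiomyocyte list, and Wnt9a (97.7 ± 0.913), Dkk3 (83.5 ± 1.26) and Wnt5b (66.9 ± 20.6) of the Wnt list (n = 3 for each gene). The Tubb3 summit lay 1113 bp upstream of the gene, in an exon of another gene. The Dkk3 promoter held a peak of its own in 2 libraries. Lipe (96.5 ± 0.905), Zfp423 (85.8 ± 5.995) and Pnpla2 (73.9 ± 19.5) were the highest-ranked promoters of the adipogenic list (n = 3 for each gene). Mcm2 (91.7 ± 1.93), E2f1 (89.2 ± 2.72) and Ccnd3 (87.7 ± 4.37) were those of the cell cycle list and Runx1 (78.9 ± 7.44), Cilp (78.7 ± 6.76) and Sox9 (60.7 ± 22.3) those of the osteochondrogenic list (n = 3 for each gene). Sema3d (79.9 ± 5.42), Krt7 (61.2 ± 33.9) and Krt8 (57.2 ± 43.2) were those of the epicardial list (n = 3 for each gene). The promoter regions at Camk2a, Rbfox3, Cacna1c, Myl4, Wnt5b, Lipe and Ccnd3 lay near transcript starts inside the gene. Sites outside promoters ranked higher at Alpl (99.8 ± 0.122) of the osteochondrogenic list, Tcf7l1 (99.5 ± 0.192) of the Wnt list, Lrrn4 (98.5 ± 0.754) of the epicardial list and Cdk6 (93.5 ± 8.13) of the cell cycle list, genes chosen after the values were seen (n = 3 for each gene). Endothelial genes had promoter sites at Ecscr (72.3 ± 20.3) and Tek (67.9 ± 28.9) and an intronic site at Pecam1 (96.2 ± 4.65; n = 3 for each gene), and Tek also had a stronger intronic site (folds 58.9, 45.8 and 92.8 in replicates 1, 3 and 4). Macrophage genes had a promoter site at Cd14 (46.3 ± 22.6) and locus sites at Cx3cr1 (99.7 ± 0.126) and Csf1r (90.6 ± 2.47; n = 3 for each gene). The Cd14 promoter held a peak of its own in 2 libraries. The Cx3cr1 site lay in an exon, 117591 bp from the nearest Cx3cr1 transcript start.

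Genes of myofibroblast activation and the TGF-β pathway were examined whatever their values. Col1a1, the main fibrillar collagen gene, had 7 consensus regions in its locus. The strongest lay 7121 bp upstream of the gene (chromosome 11, 94928585 to 94929461, mm10) with folds of 44.1, 38.0 and 90.0 in replicates 1, 3 and 4. No consensus region lay at the Col1a1 promoter, which held a peak in 2 libraries. The mice are named Col1a1-TCF21, and whether their construct adds signal at Col1a1 was not tested. Smad3, which encodes a transducer of the TGF-β signal, had 16 consensus regions. They included a site 1276 bp from an internal transcript start (chromosome 9, 63664925 to 63665860) with folds of 21.8, 13.3 and 30.1. Acta2, the α smooth muscle actin gene that marks myofibroblasts, had a site 37 bp from its start (chromosome 19, 34255237 to 34255899, folds 7.43, 7.46 and 14.6), and Ccn2 had a site 128 bp from its start (chromosome 10, 24595347 to 24596644, folds 6.93, 6.49 and 15.5). Tgfbr2 had a promoter site (chromosome 9, 116174347 to 116175650, folds 14.4, 5.19 and 20.7) and a stronger intronic one (116098970 to 116100136) with folds of 32.2, 21.7 and 53.2. The strongest site in the Tgfb1 locus lay beyond the end of the gene, in an exon of another gene and 24895 bp from the Tgfb1 start (chromosome 7, 25711198 to 25712545, folds 29.7, 22.7 and 39.6).

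Genes of the E proteins, the usual dimer partners of TCF21, had sites as well. Tcf12 had a promoter site (chromosome 9, 72111830 to 72112337, folds 7.43, 7.14 and 16.5) and a stronger intronic one (71874521 to 71875219) with folds of 26.7, 21.1 and 41.9 in replicates 1, 3 and 4. Tcf4 had an intronic one (chromosome 18, 69576229 to 69577057, folds 10.9, 6.81 and 18.4) and Tcf3 one within the gene (chromosome 10, 80418246 to 80418826, folds 5.94, 5.84 and 6.12). The other region in the Tcf3 locus lay at the promoter of a neighbouring gene. Tcf21 itself, Postn and Tgfbr1 had no consensus region, and their promoters held a peak in 0, 1 and 2 libraries.

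**Figure D4:**
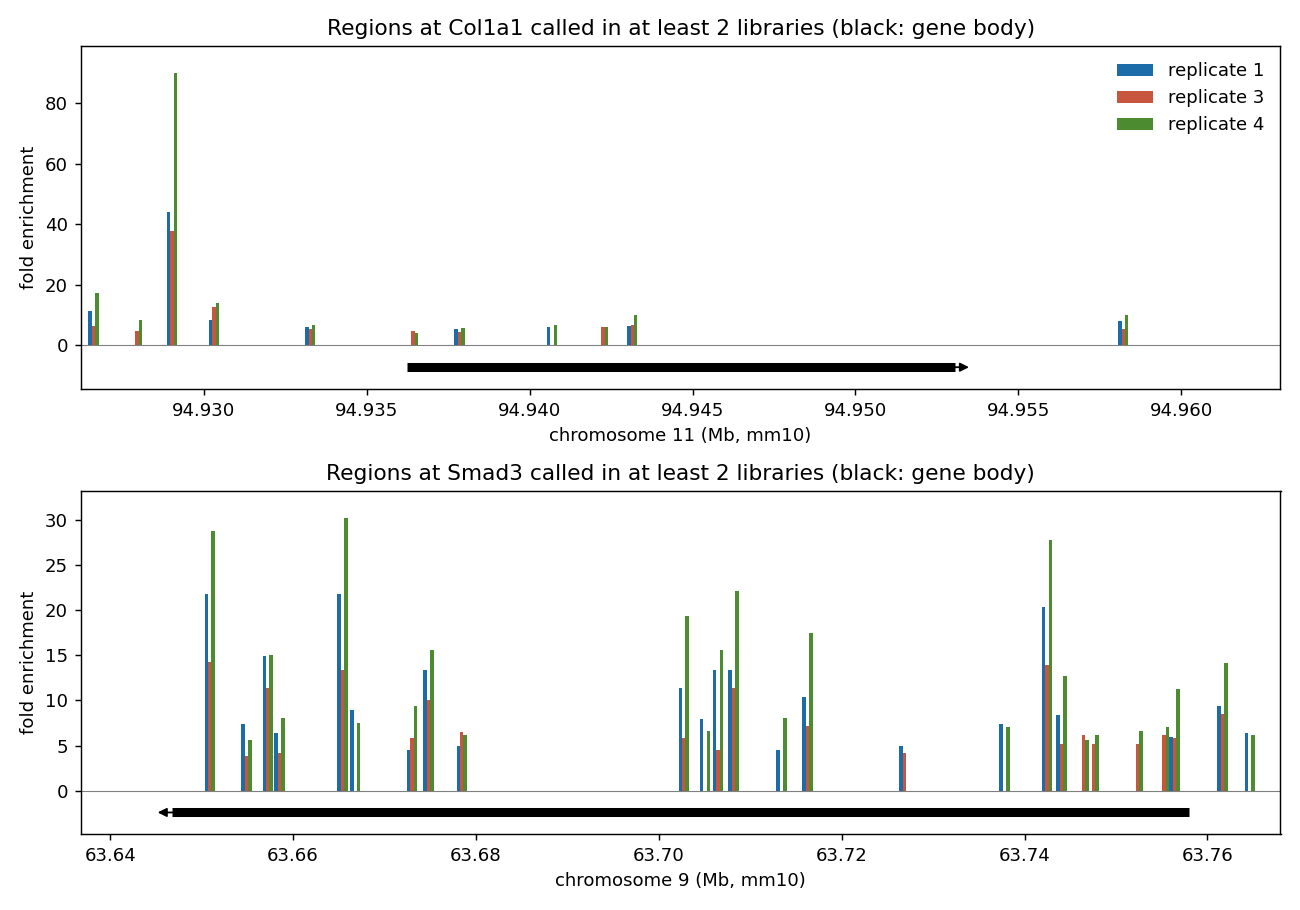
Fold (vertical axis) of the regions called in at least 2 libraries along Col1a1 and Smad3, by mm10 position (horizontal axis, Mb), with 1 bar per replicate. The strongest Col1a1 site lies upstream of the gene, and sites spread over the whole of Smad3.

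The very highest fold values lay on repeated sequence. The 10 highest consensus regions had Gm10800 (chromosome 2, 98666235 to 98667333, folds 6632.2, 4863.9 and 4762.9 in replicates 1, 3 and 4), Chl1, Gm10801, Rpusd4, Gm10718, Gm11168, Gm21738 and Tcp10c as nearest genes. In each of them 33.6 to 93.1% of the 32-base words occurred elsewhere in the chromosomes. In all, 916 consensus regions (4.89%) had more than 10% of such words. Among the 25 highest single-copy regions, chosen after the values were seen, were intronic sites at Olfml2b (folds 63.4, 44.5 and 92.3 in replicates 1, 3 and 4) and at Tek, which encodes an angiopoietin receptor (chromosome 4, 94752109 to 94753239, folds 58.9, 45.8 and 92.8). Others were a site near the TGF-β co-receptor gene Tgfbr3 (59.4, 37.3 and 79.6), and sites near the Notch target gene Heyl (44.6, 44.8 and 85.2), Col1a1 and the collagen chaperone gene Serpinh1 (47.5, 27.9 and 81.0).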

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

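Mitochondrial DNA was outside the planned measurement, and its summits were set apart because the lists held peaks on a chromosome that no comparison used. There were 45, 50 and 54 such summits in replicates 1, 3 and 4, with a highest fold of 69.3, 104 and 70.2. No explanation of them was tested.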

How the results depend on the processing

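Most results kept their call under the alternatives, and where results changed the cause was not tested. The number of peaks per library fell from a mean of 78466 to 27751 with −log10 q of at least 10, and consensus regions from 18714 to 7353, or to 7525 with 50% overlap of both peaks. Lists called by promoter occupancy went from 6 to 7–10 when libraries were left out, to 3 against genes with a peak and to 3 with GC matching. CAGCTG or CATCTG in promoter against distal summits was 0.805–0.957 when libraries were left out and 0.857 with −log10 q of at least 10. With −log10 q of at least 10 CACATG over control (0.910) and CACCTG over control (0.955) reversed, and without replicate 3 CACATG over control (0.968) did. Shuffled summit sequence reversed CAAATG (1.03), CAACTG (0.650), CACCTG (0.808), CATATG (1.28), NFI site over control (0.867), C/EBP (0.724), MEF2 (2.78), forkhead (1.77) and STAT (1.36). No paired analysis was possible because the samples form only 1 group. Without read counts, the effect of depth on list length could not be measured.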

Other observations

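TCF21 sites were sparse on the X chromosome, which carries 948 of the protein-coding genes examined. Replicates 1, 3 and 4 had 2.19, 1.75 and 4.85 regions per Mb on the X against 16.9, 23.8 and 34.5 on the autosomes. Promoters with a peak were 4.85, 4.43 and 18.4% on the X against 23.0, 22.5 and 46.9% on the autosomes, where the lowest chromosome had 15.03, 17.0 and 35.4%.

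The tests of X signal level, of background calls, of repeat copies and of each replicate's weak sites were chosen after the results were seen. A signal on the X at 0.5 of the autosomal level would fit the promoter peaks when all X genes were counted. The observed over predicted ratio was then 1.014 ± 0.054 (n = 3). For single-copy X promoters the X to autosome ratio was 0.292, 0.270 and 0.556 in replicates 1, 3 and 4. The predicted values were lower, at 0.206, 0.185 and 0.409. Autosomal promoters were not limited to single-copy ones, so the test cannot settle this explanation. The same explanation alone did not account for all regions on the X (0.584 ± 0.085, n = 3). Fewer CAGCTG sites on the X was also insufficient alone, since their density was 0.684 of the autosomal one (276.0 against 403.4 per Mb). Regions per Mb were 0.130, 0.073 and 0.141 of the autosomal value in replicates 1, 3 and 4. Whether a lower signal and fewer sites together account for all regions was not tested. Multi-copy sequence alone did not account for the few promoter peaks on the X, since 625 single-copy X promoters had a ratio of 0.373 ± 0.159 (n = 3). No other explanation was tested, and the samples give only 1 group and mix the sexes.

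Regions called in 1 library are unlikely to be all background calls with no binding site. CAGCTG was 2.23 ± 0.46 times as frequent at their summits as in flanks (n = 3). This mean over all such summits cannot tell what share of the regions are background calls, and flanks were not matched on GC. Unequal list lengths alone did not account for the regions called in 1 library, whose share fell from 73.8 to 63.5% at equal lengths. At matched fold, the CAGCTG share in regions of 3 libraries exceeded that in regions of 1 library by 16.7 ± 13.6 points over the libraries (n = 3), so sites too weak to pass in every library cannot be told apart from other causes. By replicate, the difference was 18.9 ± 5.05 points in replicate 1, 29.0 ± 8.19 in replicate 3 and 2.08 ± 4.37 in replicate 4. These SDs are over 5 parts of the fold range in 1 library and not over samples. In replicates 1 and 3 the shared regions had the higher share in every part, and in replicate 4 the direction varied between parts. The fold of 1 library measures site strength imperfectly, and regions called in 3 libraries may be stronger at the same fold. The comparison therefore cannot decide for or against weak sites in any replicate.

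The highest-ranked consensus regions may reflect reads shared between repeat copies, since 10 of 10 had over 10% of words elsewhere. CAGCTG or CATCTG at the summit was found in at least 2 libraries in 0 of these 10 and in 25 of the 25 highest single-copy regions. No biological explanation of their height was tested.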
